A study of Mus musculus with 8 samples.

How the data were processed

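RNA sequencing of mouse colonic organoids was analysed from the table the authors deposited, with 4 KO and 4 WT libraries. Per the labels' protocols, crypts were isolated with EDTA, grown in Matrigel for at most 15 passages, and RNA with an integrity number above 7.0 was made into stranded mRNA libraries from 1 µg. The deposited count values are whole numbers per gene and library, not normalized, and per the submitters' processing notes TopHat2, Bowtie2, TopHat, HTSeq and the build GRCm38 were used by the authors, with no version or role given. Whether strand was used in counting is not given in the sources used here, so overlapping and antisense genes are uncertain. In the deposited counts the value 2 was more frequent than 1 in every library (548 to 622 genes with 1 count, 673 to 772 with 2), so both mates of a read pair may have been counted. The authors' FPKM values, scaled for transcript length and depth, and the authors' TPM values, which sum to between 999972 and 999989 per library, were deposited in the same table and were described only, because tests need counts. Groups were taken from the genotype labels. Library numbers are not shared between the genotypes, so no pairing was used, and the labels give no sequencing batch.

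The table held 45777 genes by NCBI Gene ID, of which 45679 had a position in the RefSeq annotation of GRCm38. No row lacked a gene. Library totals of 37182098 to 49256171 counts set the precision: a count of 0 allows up to 3 counts, or 0.0606 to 0.0810 CPM (6 counts, or 0.121 to 0.162 CPM, if both mates were counted), and such limits cover counting error only. Libraries of 1 genotype were compared by a chi-square over genes with a mean count of at least 20, and none held identical values. Genes were filtered with filterByExpr, scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. At least 2-fold means a fitted log2 fold change of at least 1 in size. CPM is TMM-scaled, errors are the SD of 4 libraries, and the SE of a log2 fold change is its size divided by the square root of the F statistic. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01, for lists with at least 5 tested members. No camera call held with the correlation estimated per list, where the smallest adjusted p was 0.0988, and 2 lists higher and 5 lower had an unadjusted p under 0.05. With fry, which tests whether the genes of a list move on balance one way, 8 lists were higher and 16 lower. Chromosome medians were compared with 100000 random gene sets, genes within 5 Mb of Reg3a with Fisher's exact test, and library measures with two-sided exact permutation tests, with Benjamini-Hochberg adjustment over 6 measures. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

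The design, 35 gene lists and the rule for named genes were fixed before the data were examined. Of 727 list entries 726 were matched to a gene, and Prac1 was not. The rule takes genes with an adjusted p under 0.05, at least a 2-fold change, a mean of at least 5 CPM, no overlap between the libraries of the genotypes, and a symbol that is neither predicted nor a clone name nor a pseudogene. Of these it names the 13 highest and the 13 lowest log2 fold changes. In the data 17 genes qualified as higher, of which the rule took 13, and 2 as lower. It also names all Reg family members, Nnt, and up to 4 members of each other list with the smallest adjusted p under 0.05, or the 2 most abundant where none passed. Some genes that the rule takes are not reported here. Other genes are said to have been chosen after their values were seen.

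On simulated counts with 50 changed genes per fold, for KO against WT with 14791 genes run, the edgeR step recovered 60% of genes changed 1.25-fold, 72% at 1.5-fold, 86% at 2-fold and 92% at 3-fold. It called 8 unchanged genes. The 14745 unchanged genes simulated include some that the low-count filter removed before the test. The list test, with 14945 genes run, called 20 of 20 simulated lists shifted by 0.3 on the log2 scale and 0 of 20 unshifted ones. The genes of these lists were simulated independently of each other. In the data the correlation estimated per list ran from -0.136 (tuft cell) to 0.682 (mitochondrially encoded). The simulation therefore cannot show how often correlated lists are called falsely.

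Alternatives fixed before the data were examined were other scalings (DESeq2 size factors, upper quartile, library totals alone), the DESeq2 1.42.0 Wald test, limma-voom, no low-count filter and a stricter one, an adjusted p of 0.01, a test against a 2-fold change, an estimated correlation, fry, and leaving out each library in turn. Chosen after seeing the data were a per-library smooth on GC content and transcript length for the 12581 tested genes (84.2%) with both, counts thinned to the smallest total, and mitochondrial genes left out. Marker lists of lung, liver, exocrine pancreas, skeletal muscle, brain and kidney, and lists of aminoacyl-tRNA synthetases, amino acid enzymes, Hox groups and the Gsdmc family, were written after the data were seen.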

Results

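Gene expression was measured by RNA sequencing in colonic organoids, three-dimensional epithelial cultures grown from isolated crypts, of male mice aged 9 weeks. The study concerns the interleukin IL-22, Paneth cell metaplasia in ulcerative colitis and wound healing through REG3A, a secreted C-type lectin of the Reg family. Organoids in which Cre recombinase under the Villin promoter was used to remove exons 2 to 4 of Reg3a from the intestinal epithelium (KO, 4 libraries, replicates 5 to 8) were compared with organoids carrying the floxed gene without Cre-mediated deletion (WT, 4 libraries, replicates 13 to 16). All were collected 3 days after passage without further treatment, so the comparison asks which transcripts differ with the Reg3a genotype in unstimulated epithelium. Library totals lay between 37182098 counts (WT replicate 16) and 49256171 counts (WT replicate 14) and no difference between genotypes passed a test (two-sided exact permutation p = 0.571, n = 4). The labels contradict each other on replication: in one place they give 1 mouse per genotype plated in 4 wells, and in another 3 mice per genotype in technical triplicate. The 4 libraries per genotype match the 4 wells of the first statement and not 3 mice in triplicate. All p-values therefore measure the spread between these libraries, which may be technical, between wells of 1 mouse. Genotype is not separable from mouse or organoid line. The first principal component of log2 CPM held 32.4% of the variance and separated KO from WT. Pairs of WT libraries had a chi-square per degree of freedom of 11.1 to 24.7, pairs of KO libraries 4.96 to 10.7, and pairs of 1 KO and 1 WT library 25.7 to 41.5.

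The targeted gene could not be used to check the labels. Reg3a (NCBI Gene ID 19694, chromosome 6, 78380709 to 78383839, GRCm38) had 0 counts in all 8 libraries. Counting error alone allows at most 0.0810 CPM for a count of 0 in the shallowest library, WT replicate 16, and 0.0606 CPM in the deepest, WT replicate 14, or 0.162 and 0.121 CPM if both mates of each read pair were counted. The family members Reg1, Reg2, Reg3d and Reg3g, on the same chromosome, also had 0 counts in every library. Reg3b had 4 counts in KO replicate 5, 4 in KO replicate 7 and none elsewhere. Reg4, on chromosome 3, was the only member with enough counts to test, at 1.43 ± 0.915 CPM in KO and 2.55 ± 0.966 CPM in WT (SD, n = 4). Its log2 fold change was -0.84 ± 0.37 (SE, edgeR adjusted p = 0.152), or -1.38 with an edgeR adjusted p = 0.0173 when KO replicate 7 was left out. Adjusted over the list alone, in which Reg4 was the 1 gene tested, it counted as lower. A Reg3a fold change cannot be given, and a difference in Reg3a RNA was not detectable at this depth in either direction.

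The genotypes differed across a broad set of genes, most of them by less than 2-fold. Of 14945 genes tested, 1140 were higher and 1234 lower in KO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold differences were found for 120 genes higher and 44 genes lower in KO. The most raised of the genes named for a change of at least 2-fold and a mean of at least 5 CPM was S100g, which encodes the calcium-binding protein calbindin-D9k, at 19.2 ± 3.40 CPM in KO and 6.27 ± 1.21 CPM in WT (SD, n = 4), a log2 fold change of 1.61 ± 0.14 (SE, edgeR adjusted p = 1.2e-05). Gsdmc2, of the gasdermin family (chromosome 15, 63824328 to 63845193), stood at 39.8 ± 2.71 CPM in KO and 13.7 ± 1.63 CPM in WT. Its neighbours Gsdmc3 and Gsdmc4 had log2 fold changes of 1.36 ± 0.10 and 1.34 ± 0.10 (SE), and the split of reads between these similar copies is uncertain. Ano3, of the anoctamin family, rose by 1.41 ± 0.09 on the log2 scale, and the homeobox gene Hoxb6 by 1.40 ± 0.14. Cyp4f14, a cytochrome P450 gene, Abat, which breaks down the transmitter GABA, and Hsd3b3, a steroid dehydrogenase gene, had log2 fold changes of 1.30, 1.17 and 1.15. Car12, a carbonic anhydrase gene, Enpp4 and Mylk, the myosin light chain kinase gene, followed at 1.13, 1.12 and 1.12. In the other direction, 2 genes met the same rule. Nos2, the inducible nitric oxide synthase gene, fell from 34.3 ± 4.60 CPM in WT to 16.3 ± 3.05 CPM in KO (log2 fold change -1.08 ± 0.12 SE, edgeR adjusted p = 7.7e-05), and Cd177 fell from 32.2 ± 5.14 to 15.7 ± 2.90 CPM (-1.04 ± 0.13). The numbers of genes depended on single libraries: 757 were higher without KO replicate 5, 696 higher and 724 lower without KO replicate 8, and 808 lower without WT replicate 13. After a smooth on GC content and length, 1882 of 12581 genes were lower. With only genes of at least 1 CPM in 4 libraries and a mean of at least 5 CPM tested, 23 were at least 2-fold higher and 5 lower, and a test against a 2-fold change itself passed 15 higher and 1 lower.

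**Figure D1:**
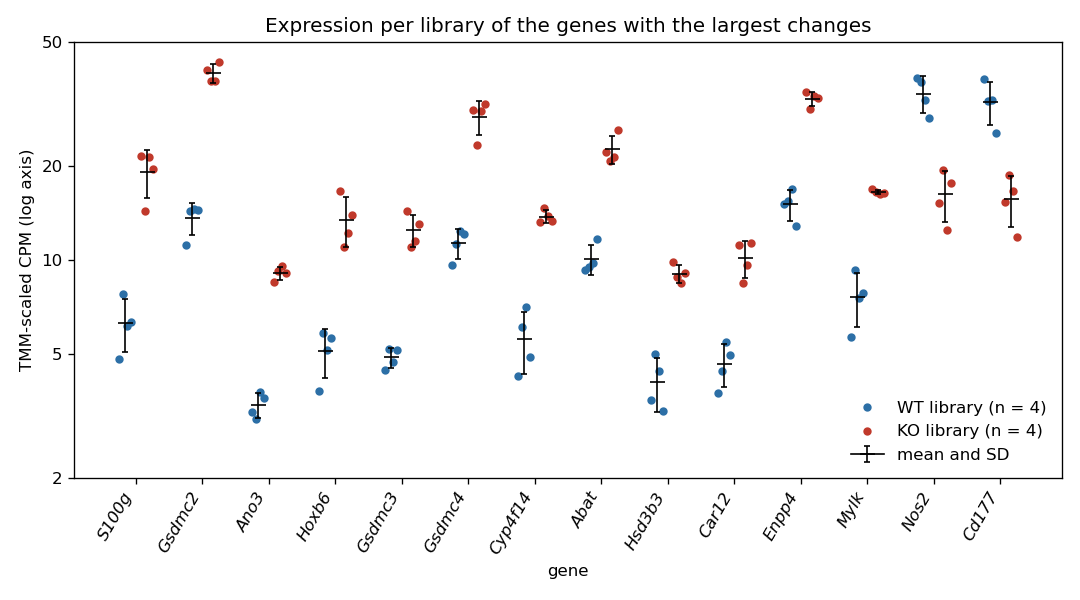
TMM-scaled CPM on a log axis for the genes named as most raised and most lowered in KO (x axis), with 1 point per library (4 KO, 4 WT) and the mean with its SD as bars. All KO points lie above all WT points for the genes from S100g to Mylk and below them for Nos2 and Cd177.

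Genes of the cell cycle were lower in KO. All 24 tested members of the mitosis list fell, also when adjusted over the list alone, with a median log2 fold change of -0.33. Aurkb, the Aurora B kinase gene, fell from 72.9 ± 4.80 CPM in WT to 49.7 ± 2.62 CPM in KO (SD, n = 4; log2 fold change -0.55 ± 0.06 SE, edgeR adjusted p = 3.5e-05). Top2a (-0.40 ± 0.05), the spindle checkpoint kinase gene Bub1b (-0.38 ± 0.05) and Cdca8 (-0.36 ± 0.05) fell with it. Of 24 tested DNA replication genes 20 fell and none rose (23 fell adjusted over the list alone), among them Uhrf1, Mcm5, Mcm3 and Mcm7, the last 3 subunits of the replicative helicase, at log2 fold changes of -0.39, -0.37, -0.36 and -0.32. The camera set test called the mitosis list lower (adjusted p = 4.5e-16; adjusted p = 0.172 with an estimated correlation) and the DNA replication list lower (adjusted p = 2.1e-14; adjusted p = 0.0988 with an estimated correlation). Of 15 tested crypt stem cell genes 6 fell and 1 rose (7 and 1 adjusted over the list alone). The stem cell marker Lgr5 fell from 40.7 ± 2.23 to 28.9 ± 1.26 CPM, the water channel gene Aqp4 from 482 ± 51.8 to 378 ± 10.2 CPM, and Smoc2 from 1.44 ± 0.289 to 0.693 ± 0.112 CPM. Ephb3, a receptor gene that positions crypt cells, fell by 0.43 on the log2 scale. These genes were called lower as a list (camera adjusted p = 0.00453; adjusted p = 0.208 with an estimated correlation). Wnt target genes split, with 3 higher and 3 lower of 13 tested (3 and 3 adjusted over the list alone): Sp5 (log2 fold change 0.93), Rnf43 (0.21) and Ccnd1 (0.18) rose while Lgr5 fell, and the list did not pass the test (camera adjusted p = 0.578).

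Genes of the absorptive colonocyte, the main differentiated cell of the colonic surface, were higher in KO. Of 27 tested members 17 rose and 2 fell (18 and 2 adjusted over the list alone), with a median log2 fold change of 0.37. The carbonic anhydrase gene Car1 rose from 888 ± 97.0 CPM in WT to 1730 ± 49.2 CPM in KO (SD, n = 4; log2 fold change 0.96 ± 0.06 SE, edgeR adjusted p = 1.4e-06). The cytochrome P450 gene Cyp2c55 rose from 404 ± 51.5 to 743 ± 44.7 CPM, the surface keratin gene Krt20 from 41.8 ± 2.85 to 70.7 ± 4.94 CPM, and Lypd8, which encodes a secreted inhibitor of bacterial motility, from 2092 ± 130 to 2809 ± 44.3 CPM. The list was called higher (camera adjusted p = 4.0e-08; adjusted p = 0.0988 with an estimated correlation). The 2 members that fell, Aqp8 and Mxd1, were named after their values were seen. Aqp8, a water channel gene, fell from 22.8 ± 14.0 to 9.37 ± 2.09 CPM (log2 fold change -1.28 ± 0.37 SE, edgeR adjusted p = 0.0314), and Mxd1 fell by 0.25 on the log2 scale. The WT libraries lay between 6.59 and 37.2 CPM for Aqp8 and overlapped those of KO. Of 23 tested targets of xenobiotic receptors and NRF2, 11 were higher and 3 lower, with the same counts adjusted over the list alone. They included the bilirubin-conjugating enzyme gene Ugt1a1 (log2 fold change 0.92 ± 0.06), Aldh1a1 (0.86 ± 0.08), Gsta1 (0.47 ± 0.05) and Nqo1 (0.26 ± 0.04), and the list was called higher (camera adjusted p = 0.0132; adjusted p = 0.279 with an estimated correlation). Cyp2c55, Ugt1a1 and Gsta1 belong to families of similar genes, so their share of reads is uncertain. For fatty acid oxidation and PPAR targets, 6 of 21 tested genes rose and 1 fell (7 and 1 adjusted over the list alone), with Ehhadh (0.36) and Cpt2 (0.20) among those that rose (camera adjusted p = 0.0414; adjusted p = 0.279 with an estimated correlation). That call ended without KO replicate 5, WT replicate 13 or WT replicate 15, at camera adjusted p = 0.0502, 0.111 and 0.0590.

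**Figure D2:**
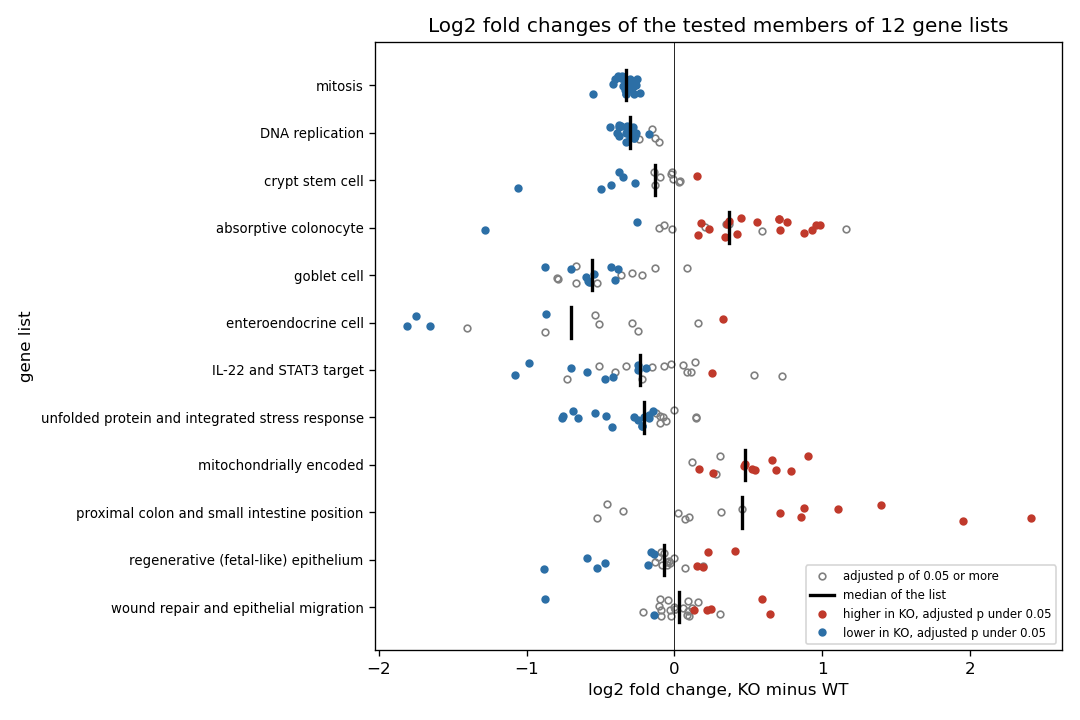
Log2 fold changes (KO minus WT, x axis) of the tested members of 12 gene lists (y axis), 1 point per gene, filled where the adjusted p was under 0.05, with the median of each list as a vertical bar. All 24 mitosis genes lie below 0, while 17 of 27 absorptive colonocyte genes were called higher.

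Transcripts of the mitochondrial genome were more abundant in KO. Of its 13 protein genes 10 rose and none fell (12 adjusted over the list alone), at a median log2 fold change of 0.48. ND4L, a gene for a complex I subunit, rose by 0.91 ± 0.08 on the log2 scale, ND4 by 0.79 ± 0.09, CYTB by 0.68 ± 0.08, and COX1 rose from 5085 ± 378 CPM in WT to 7314 ± 990 CPM in KO (SD, n = 4). The list was called higher (camera adjusted p = 2.4e-07; adjusted p = 0.273 with an estimated correlation). Mitochondrial transcripts made up 1.57% ± 0.159 of counts in KO and 1.14% ± 0.0989 in WT (SD, n = 4), and every KO library exceeded every WT library (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 libraries allow). The share of counts on protein-coding genes was lower in KO, at 97.4% ± 0.0557 against 97.7% ± 0.148, and that on ribosomal RNA higher, at 0.107% ± 0.00674 against 0.0876% ± 0.0112 (SD, n = 4), each with the same exact permutation p = 0.0286. Adjusted over the 6 library measures compared, these 3 p-values became 0.0571 and did not pass. These shares moved with the genotype, and so with each gene group described here. None of the 24 tested nuclear genes of oxidative phosphorylation passed the edgeR test, also when adjusted over the list alone. Atp5b stood at 2035 ± 18.2 CPM in KO and 2125 ± 32.6 CPM in WT, and Atp5a1 at 1468 ± 13.6 and 1465 ± 28.5 CPM. The camera direction of that list was lower (adjusted p = 0.968), although its median and mean log2 fold changes, 0.0048 and 0.0018, were above 0.

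Of the secretory lineages, goblet cell genes were lower in KO, while the list calls of Paneth and enteroendocrine cells depended on the setting and that of tuft cells was made with fry only. Of 20 tested goblet cell genes 9 fell and none rose (16 fell adjusted over the list alone), with a median log2 fold change of -0.56. The trefoil peptide gene Tff3 fell from 31.1 ± 3.63 CPM in WT to 16.9 ± 2.47 CPM in KO (SD, n = 4; log2 fold change -0.88 ± 0.10 SE, edgeR adjusted p = 8.95e-05). Agr2, a protein disulfide isomerase gene, fell by 0.58 on the log2 scale, Bcas1 by 0.55 and Fcgbp, a mucus protein gene, by 0.43. Together the goblet cell genes were called lower (camera adjusted p = 4.3e-07; adjusted p = 0.232 with an estimated correlation). Their mean log2 CPM, relative to the mean of all libraries, varied widely within each genotype. It ran from -0.47 (KO replicate 8) to -0.036 (KO replicate 7), and from 0.0059 (WT replicate 16) to 0.44 (WT replicate 13). Of 12 tested enteroendocrine genes 4 fell and 1 rose, with the same counts adjusted over the list alone. The proglucagon gene Gcg fell from 2.19 ± 0.633 to 0.619 ± 0.256 CPM, the peptide YY gene Pyy from 11.6 ± 2.55 to 6.35 ± 1.82 CPM and the transcription factor gene Insm1 from 0.575 ± 0.236 to 0.170 ± 0.0687 CPM (camera adjusted p = 0.0204; adjusted p = 0.304 with an estimated correlation). That list was not called after a smooth on GC content and length (camera adjusted p = 0.0721), although its median log2 fold change was -0.70 before and -0.66 after it. Cpe, a prohormone-processing enzyme gene, rose by 0.33, a call that ended without KO replicate 5, KO replicate 8 or WT replicate 13 (edgeR adjusted p = 0.0547, 0.0909 and 0.0809). Of 12 tested Paneth and deep crypt secretory cell genes 3 fell and 1 rose (4 and 1 adjusted over the list alone). Those called were not antimicrobial peptide genes: Nupr1, a stress-induced gene (-0.47), the receptor tyrosine kinase gene Kit (-1.11) and the Notch ligand gene Dll4 (-0.43) fell, and the lipase-related Pnliprp2 (0.62) rose. The Dll4 call ended without KO replicate 5, 6 or 7 or WT replicate 13 or 15 (edgeR adjusted p = 0.0507 to 0.120), with no low-count filter (0.0655) and with counts thinned to the smallest library (0.0501). That of Pnliprp2 ended without KO replicate 6, 7 or 8 or WT replicate 13 or 14 (0.0528 to 0.0836). The list was called lower (camera adjusted p = 0.0448; adjusted p = 0.348 with an estimated correlation), but not without KO replicate 5 (0.103), KO replicate 8 (0.0589), WT replicate 13 (0.0526), WT replicate 14 (0.0918) or WT replicate 15 (0.124), nor among the 12581 genes with known GC content and length, before (0.0507) or after (0.139) a smooth on both. Among 5 tested tuft cell genes 1 fell, also when adjusted over the list alone, namely Avil, from 0.779 ± 0.136 to 0.412 ± 0.138 CPM. Camera did not call the list (adjusted p = 0.296), while fry called it lower (adjusted p = 0.0375). The Avil call ended without KO replicate 5, 7 or 8 or WT replicate 13, 15 or 16, at edgeR adjusted p = 0.0779, 0.134, 0.137, 0.130, 0.0651 and 0.0866. It also ended with no low-count filter (0.0604) or thinned counts (0.0599).

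Targets of IL-22 and STAT3, the pathway named in the study's title, were on balance lower in KO, although no IL-22 was added. Of 24 tested members 9 fell and 1 rose (10 and 2 adjusted over the list alone). Besides Nos2, the membrane mucin gene Muc1 fell from 38.5 ± 9.37 CPM in WT to 19.4 ± 3.07 CPM in KO and the phospholipase gene Pla2g5 from 31.2 ± 2.29 to 22.6 ± 1.48 CPM (SD, n = 4). Socs3, a feedback inhibitor gene of the pathway, fell by 0.70 on the log2 scale. As a list these targets were called lower (camera adjusted p = 0.0132; adjusted p = 0.156 with an estimated correlation). The mean log2 CPM of the tested members, relative to the mean of the 8 libraries, overlapped between genotypes. It was -0.0127 in WT replicate 15 and -0.0109 in KO replicate 6. The same measure also overlapped for the called xenobiotic list (-0.0056 in KO replicate 6, -0.0036 in WT replicate 14). So it did for the glycolysis and hypoxia list (-0.00037 in KO replicate 6, -0.0019 in WT replicate 13) and the Paneth list (0.028 in KO replicate 7, -0.083 in WT replicate 16). Reg3b and Reg3g, also on the IL-22 and STAT3 list, had too few counts to test. Of 20 tested NF-kB and inflammatory genes 2 rose and 6 fell (4 and 6 adjusted over the list alone). Camera did not call the list (adjusted p = 0.134), while fry called it lower (adjusted p = 0.0125). The neutrophil chemokine gene Cxcl1 fell from 1.57 ± 0.325 to 0.385 ± 0.118 CPM (log2 fold change -2.02 ± 0.26 SE, edgeR adjusted p = 2.0e-04), Tnf fell by 0.59 and Cxcl16 by 0.35 on the log2 scale, and Tnfaip2 rose by 0.57. Antigen presentation genes were called higher as a list (camera adjusted p = 0.0239; adjusted p = 0.304 with an estimated correlation), with 2 of 10 tested members higher and none lower (4 and none adjusted over the list alone). They were H2-Q2 (0.45 ± 0.06), whose reads are hard to separate from those of related genes, and the peptide-loading factor gene Tapbp (0.19 ± 0.05), which was not called without any 1 of the 4 KO libraries or WT replicate 13, at edgeR adjusted p = 0.0559 to 0.0795. The list call ended without WT replicate 13 or 15 and with the stricter low-count filter, at camera adjusted p = 0.0675, 0.0755 and 0.0613. The interferon response list was not called (camera adjusted p = 0.344): 3 of 32 tested genes rose and 1, Ifit1bl1, fell by 0.52 on the log2 scale, with the same counts adjusted over the list alone.

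**Figure D3:**
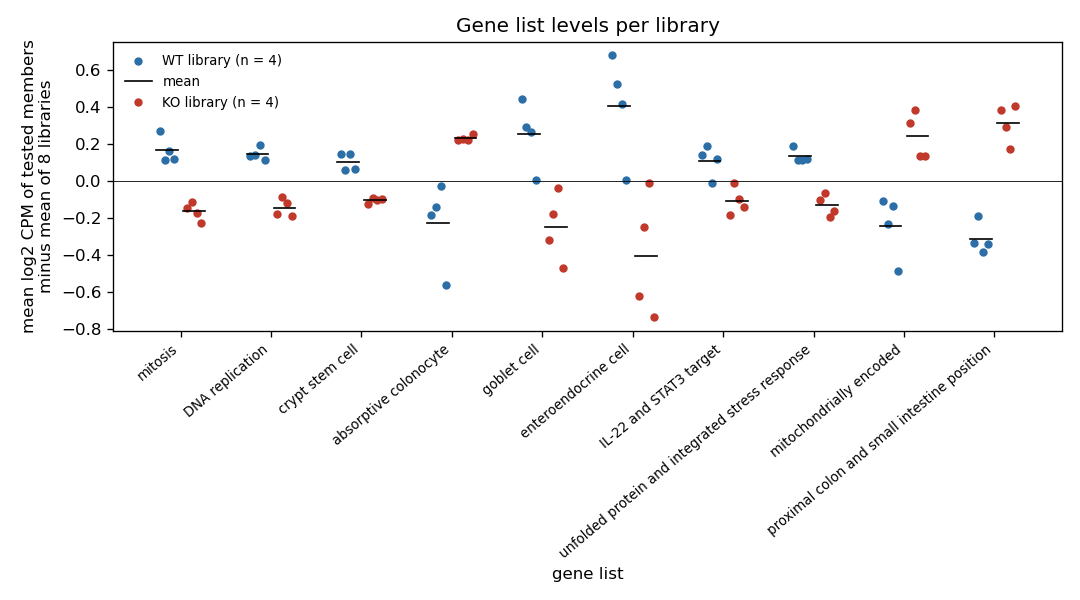
Mean log2 CPM of the tested members of 10 gene lists (x axis) in each library, relative to the mean of the 8 libraries, with 1 point per library (4 KO, 4 WT) and group means as lines. The mitosis score lies between -0.23 and -0.11 in KO and between 0.11 and 0.27 in WT, and the absorptive colonocyte score between 0.22 and 0.25 in KO and between -0.56 and -0.028 in WT.

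Genes of the unfolded protein and integrated stress responses were lower in KO. Of 23 tested members 15 fell and none rose (15 and 1 adjusted over the list alone). Atf3 fell from 54.0 ± 1.20 CPM in WT to 33.5 ± 3.23 CPM in KO (SD, n = 4; log2 fold change -0.69 ± 0.06 SE, edgeR adjusted p = 1.5e-05). Atf4, the central transcription factor gene of the integrated stress response, fell from 194 ± 10.2 to 145 ± 7.28 CPM, its pro-apoptotic target Ddit3 from 20.7 ± 2.44 to 12.2 ± 1.47 CPM and the asparagine synthetase gene Asns from 136 ± 15.5 to 93.4 ± 6.52 CPM. Camera called the list lower (adjusted p = 1.3e-07; adjusted p = 0.156 with an estimated correlation). The immediate early and heat shock list was also called lower (camera adjusted p = 0.00453; adjusted p = 0.273 with an estimated correlation), with 5 of 18 tested genes lower, among them Atf3 and Jun (-0.26), and 1 higher (8 and 1 adjusted over the list alone). In the cholesterol synthesis list 5 of 22 tested genes fell and 2 rose (6 and 2 adjusted over the list alone). The sterol-regulated Insig1 (-0.33), Pmvk (-0.33) and Fdps (-0.24) fell (camera adjusted p = 0.00453, lower; adjusted p = 0.195 with an estimated correlation). Of 23 tested glycolysis and hypoxia genes 6 fell and 1 rose (7 and 1 adjusted over the list alone), with Pfkfb3 (-0.36), Ndrg1 (-0.24) and Pgk1 (-0.16) lower and the hypoxia-induced Car9 (0.18) higher (camera adjusted p = 0.0194, lower; adjusted p = 0.396 with an estimated correlation). This call ended without KO replicate 7, WT replicate 14 or WT replicate 16, at camera adjusted p = 0.0594, 0.0505 and 0.0538. It also ended after a smooth on GC content and length (camera adjusted p = 0.0554), with a median log2 fold change of -0.077 before and -0.072 after it. The p53 target list was called higher (camera adjusted p = 0.0175; adjusted p = 0.232 with an estimated correlation), but its 20 tested members went both ways, 6 higher and 4 lower (10 and 4 adjusted over the list alone), and it was not called with the stricter low-count filter (0.0776). Cdkn2a, a cell cycle inhibitor gene that also encodes ARF, was placed in this list but is not an established p53 target. It rose from 1.26 ± 0.285 to 3.11 ± 0.708 CPM, a log2 fold change of 1.30 against a list mean of 0.11. Ccng1 rose by 0.27 on the log2 scale, while the pro-apoptotic Pmaip1 (-0.39) and Plk2 (-0.26) fell.

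Genes of wound repair and of regenerating epithelium were not called as groups by camera with all libraries, but fry called the regenerative list lower (adjusted p = 0.0436). Of 26 tested wound repair and migration genes 5 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.344). The fibronectin gene Fn1 rose from 9.65 ± 1.60 CPM in WT to 14.5 ± 2.01 CPM in KO (SD, n = 4), and the hemidesmosome gene Itgb4 (log2 fold change 0.25 ± 0.06) and the laminin gene Lama3 (0.22 ± 0.04) rose too, while Tff3 fell. Of 23 tested genes of the regenerative, fetal-like program 4 rose and 7 fell (5 and 9 adjusted over the list alone; camera adjusted p = 0.0802). Cldn4 fell from 720 ± 58.0 to 477 ± 31.8 CPM and the YAP target Ccn1 from 14.1 ± 1.10 to 9.79 ± 1.64 CPM, whereas the EGF receptor ligand gene Ereg rose from 22.6 ± 3.32 to 30.1 ± 1.89 CPM. This list passed, as lower, without KO replicate 6 or without WT replicate 16, at camera adjusted p = 0.0444 and 0.0391 (adjusted p = 0.438 with an estimated correlation and all libraries). For EGF receptor ligands and targets, 1 of 21 tested genes rose and 2 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.351), namely Ereg, Dusp4 (-0.30) and Errfi1 (-0.25). The tight junction list had 3 of 21 genes higher and 7 lower (3 and 8 adjusted over the list alone; camera adjusted p = 0.108), including Ocln (-0.27), Marveld2 (-0.28) and Dsc2 (0.23). The Notch list had 2 of 13 higher and 3 lower (3 and 5 adjusted over the list alone; camera adjusted p = 0.578), with the ligand gene Jag1 (0.50) among those higher. The BMP and TGF-beta list had 4 of 12 higher and 1 lower (4 and 2 adjusted over the list alone; camera adjusted p = 0.133), with Smad6 (0.80) higher and Id2 (-0.28) lower. Fry called the EGF receptor and tight junction lists lower (adjusted p = 0.0436 and 0.0248) and the BMP and TGF-beta list higher (0.0264). It did not call the wound repair and Notch lists (0.111 and 0.784).

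Genes listed for proximal colon and small intestine were higher in KO. Of 15 tested members 7 rose and none fell (8 adjusted over the list alone), with a median log2 fold change of 0.46. Hoxb8 rose from 1.51 ± 0.491 CPM in WT to 5.82 ± 1.23 CPM in KO (SD, n = 4; log2 fold change 1.95 ± 0.20 SE, edgeR adjusted p = 3.8e-05), Hoxb6 (chromosome 11, 96292814 to 96301569) from 5.09 ± 0.913 to 13.4 ± 2.44 CPM, and the brush border metalloprotease gene Mep1a from 31.9 ± 3.85 to 57.8 ± 2.78 CPM. Cyp2c55 belongs to this list and to the colonocyte list. The members Hoxb5, Hoxb6 and Hoxb8, all higher, are neighbours on chromosome 11, so their rises may not be independent. Hoxa5 and Hoxa7 of the list did not pass (log2 fold changes 0.072 and 0.098), while Osr2, Mep1a and Cyp2c55, on other chromosomes, rose. Hoxb5, Hoxa5, Hoxa7 and Osr2 were named after their values were seen. The list was called higher (camera adjusted p = 1.2e-04; adjusted p = 0.0988 with an estimated correlation). Distal position genes were not called (camera adjusted p = 0.578): 2 of 11 tested members rose, among them Hoxb9 from 17.3 ± 1.74 to 29.8 ± 4.22 CPM, and none fell, with the same counts adjusted over the list alone.

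Markers of other cell types were scarce. Only 2 of 15 fibroblast and smooth muscle genes, 4 of 18 immune genes and 2 of 14 endothelial, glial and neuronal genes had enough counts to test, too few for a list test. Over all genes and adjusted over the list alone alike, none of the first or the last kind passed the edgeR test. In the immune list 1 gene fell, Laptm5, from 7.01 ± 1.52 CPM in WT to 3.76 ± 0.382 CPM in KO (SD, n = 4). Pdgfrb stood at 6.16 ± 0.518 CPM in KO and 5.28 ± 1.08 CPM in WT, Acta2 at 0.207 ± 0.143 and 0.209 ± 0.118 CPM, and Vwf at 3.55 ± 0.509 and 3.88 ± 0.599 CPM. KO replicate 6 stood apart in holding transcripts typical of lung, with 1090 counts of the surfactant protein gene Sftpc and 434 of Scgb1a1, against 0 in the other 7 libraries, and without it 976 genes were higher and 1038 lower. Of 4 tested sex-linked markers the Y-linked Eif2s3y fell from 87.9 ± 7.77 to 54.0 ± 2.04 CPM and no other passed, also when adjusted over the list alone. The substrain marker Nnt, which encodes a mitochondrial transhydrogenase, was 18.4 ± 0.817 CPM in WT and 13.5 ± 0.122 CPM in KO (log2 fold change -0.44 ± 0.06 SE, edgeR adjusted p = 2.0e-04).

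The share of genes called near the targeted gene was close to that elsewhere. Within 5 Mb of Reg3a 4 of 25 tested genes were called (16.0%, 2 higher and 2 lower) against 15.9% elsewhere (two-sided Fisher exact p = 1). These 4, Mthfd2, Hk2, Sema4f and Dqx1, were named after their values were seen, and Mthfd2, a mitochondrial one-carbon enzyme gene, had the smallest adjusted p, with a log2 fold change of -0.69 ± 0.08 (SE, edgeR adjusted p = 8.6e-05). St3gal5, also chosen after its values were seen, lies outside this window on the same chromosome (72097552 to 72154571) and had 26 to 38 counts in each KO library and 0 in each WT library. Median log2 fold changes of chromosomes 1 to 19 and X lay between -0.022 and 0.022. Chromosomes 2 (0.013, adjusted p = 0.048) and 13 (0.022, adjusted p = 0.03) passed a permutation test over 100000 random gene sets at these small medians. The 23 tested genes of the mitochondrial genome had a median of 0.44 (permutation p = 1e-05, the smallest these resamples can give).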

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

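The lung marker list, the other tissue lists and both lung measures were chosen after lung transcripts had been seen in KO replicate 6. In 323 groups of 4 libraries, 16 had a library far from the other 3, where chance gives about 1 in 20, or 16.15, so no more were found than chance gives. A library lay below the other 3 for Gsdmc2 (11.2 CPM in WT replicate 13, others at least 14.3), Bub1b (59.7 CPM in KO replicate 7, others at least 62.2), Ereg (27.2 CPM in KO replicate 5, others at least 30.8), Tnfaip2 (15.2 CPM in WT replicate 15, others at least 18.0), Gsta1 (151 CPM in KO replicate 6, others at least 162) and Hes1 (83.8 CPM in WT replicate 15, others at least 88.5). A library lay above the other 3 for Smoc2 (1.87 CPM in WT replicate 15, others at most 1.33), Cdca8 (58.4 CPM in KO replicate 6, others at most 55.7), Mcm7 (94.6 CPM in KO replicate 6, others at most 86.5), Fn1 (17.5 CPM in KO replicate 7, others at most 13.8), Pmvk (104 CPM in WT replicate 16, others at most 95.2) and Acta2 (0.384 CPM in WT replicate 13, others at most 0.162). Among list scores, relative to the mean of 8 libraries, the EGF receptor list was at 0.019 in KO replicate 6 (others at most -0.021) and the stress response list at 0.19 in WT replicate 13 (others at most 0.12). The Notch list was at -0.064 in KO replicate 8 (others at least -0.023) and the immediate early list at -0.19 in KO replicate 7 (others at least -0.066).

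KO replicate 6 held lung transcripts that no other library held: Sftpc at 1090 counts (22.5 CPM), Scgb1a1 at 434, Sftpa1 at 180, Sftpb at 150, Lamp3 at 34 and Scgb3a2 at 9, each at 0 elsewhere, and 29 genes with at least 20 counts there and at most 3 in each other library held 0.0130% of its counts. The first measure set for lung RNA as the source asked that at least 8 of the 16 markers be above 3 counts in KO replicate 6 alone, and gave 6, between its bounds: 8 of the 16 are above 3 counts in all libraries, and Foxj1 and Cxcl15 reach 11 counts in another library (KO replicate 8 and WT replicate 15). After that result was known, a second measure was chosen, the markers whose highest CPM of the 8 libraries was in KO replicate 6, and gave 12 of 16, so it is weaker evidence than a measure fixed in advance, and lung RNA or reads may be the source. Reads of other tissues were first taken as excluded on 5 tissue lists and were left open after the endothelial value was seen: at most 8.33% of the markers of liver, exocrine pancreas and brain, and 0 of those of skeletal muscle and kidney, were above 3 counts in KO replicate 6 alone, below the bound set for that source, but 28.6% of the endothelial, glial and neuronal markers (4 of 14, all endothelial, namely Cdh5, Kdr, Pecam1 and Plvap) reached it, while 16.7% of immune and 13.3% of fibroblast markers did not, and lung holds such cells too. By the second measure the 5 tissue lists had at most 16.7%, and the endothelial, fibroblast and immune lists 35.7%, 33.3% and 22.2%.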

How the results depend on the processing

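The smooth on GC content and length, the thinned counts and the fit without mitochondrial genes were chosen after seeing the data. No paired analysis was possible because the library numbers 5 to 8 and 13 to 16 are not shared between the genotypes. The 4 gene counts stayed within 1.5 times their values under the other scalings, the DESeq2 Wald test, limma-voom, no low-count filter, thinned counts and mitochondrial genes left out. With the GC and length smooth 1882 genes were lower, and the cause was not tested. An adjusted p of 0.01 left 562 higher and 597 lower, with 28 at least 2-fold lower, by construction. With fewer genes tested by the stricter filter, 23 were at least 2-fold higher and 5 lower, and a test against a 2-fold change gave 15 and 1. Without 1 library the numbers ranged from 696 to 1386 higher and from 724 to 1404 lower, lowest without KO replicate 8 and highest without WT replicate 15, with 757 higher without KO replicate 5 and 808 lower without WT replicate 13. At least 2-fold counts ranged from 103 to 142 higher and from 35 to 49 lower, and called lists from 5 to 7 higher and from 9 to 12 lower. With an estimated correlation 0 lists were called higher and 0 lower by camera, and fry called 8 and 16. Fry kept the 18 camera calls and added 6: the tuft, regenerative, EGF receptor, NF-kB and tight junction lists as lower and the BMP and TGF-beta list as higher. The stricter filter ended the calls of the antigen presentation and p53 lists and left under 5 tested members of the Paneth and enteroendocrine lists, which were then not tested. The enteroendocrine and glycolysis lists were not called with the GC and length smooth, although their medians hardly moved (-0.70 to -0.66 and -0.077 to -0.072) and all their members kept their sign. On the same genes without the smooth both lists were called (camera adjusted p = 0.0244 and 0.0218), so the smooth itself ended these calls. GC or length bias may therefore have contributed to these 2 calls, although it left the size of the medians almost unchanged. The Paneth list was not called with the smooth either, but already missed the threshold on the 12581 genes with GC content and length before correction (camera adjusted p = 0.0507), as did the fatty acid list (0.0504), which passed with the smooth (0.0457). Over 125 named genes and 2226 alternative values, 2152 kept their direction and side of the threshold, 68 in 16 genes kept direction but lost the call, and 1, Reg4 without KO replicate 7, gained it. The sign turned in 5 values of 2 genes near 0 that were not called. Atp5a1 ranged from -0.0067 to 0.016 without 1 library, and Acta2 from -0.29 to 0.45, with 0.0012 under library totals alone and 0.0064 with the smooth. Among chromosomes 1 to 19 and X the median farthest below 0, that of chromosome 18, went from -0.022 to -0.014 among genes of at least 5 CPM, where chromosomes 7 and 17 passed beside 2 and 13 (adjusted p = 0.016 and 0.013). Reg3a gave no value in any alternative, and depth limits what can be said of it and of the other Reg genes at 0.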

Other observations

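Tests on the synthetases, amino acid enzymes, Hox groups, Gsdmc family, genes seen in 1 genotype and windows along chromosomes, and the smooth on GC content and length, were chosen after the data were seen, as were the genes named for them. Cytosolic aminoacyl-tRNA synthetase genes, whose enzymes load amino acids onto tRNA, were lower in KO: 11 of 20 tested fell and none rose (edgeR, Fisher exact p = 9.7e-08 against other tested genes), among them Cars (-0.49 ± 0.04 SE), Lars (-0.49 ± 0.05) and Yars (-0.42 ± 0.05). Of 12 enzymes of amino acid and one-carbon synthesis 8 fell (Fisher exact p = 7.7e-07), including Mthfd2 from 42.4 ± 2.41 CPM in WT to 26.3 ± 3.40 CPM in KO, Shmt2 from 170 ± 9.41 to 119 ± 2.16 CPM and Psat1 from 126 ± 9.40 to 91.0 ± 4.15 CPM (SD, n = 4), while Cth rose by 0.42 on the log2 scale. Ide, the insulin-degrading enzyme gene, fell from 117 ± 6.42 to 68.8 ± 3.04 CPM (log2 fold change -0.77 ± 0.05 SE, edgeR adjusted p = 1.4e-06). These p-values come from genes grouped after their direction was known, so they describe the groups and do not test them independently.

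Pax2, a transcription factor gene, had 52 to 86 counts in each KO library and 0 in each WT library, at least 21.6-fold higher (10.8-fold if both mates of a pair were counted), and St3gal5, a ganglioside synthase gene on the chromosome of Reg3a, had 26 to 38 against 0, at least 9.75-fold higher (4.88-fold if both mates were counted), with a floor of 3 counts per library, or 6 with both mates. Tbx3 stood at 3.36 ± 0.733 CPM in KO and 0.622 ± 0.0737 CPM in WT, and Osr2, a member of the proximal position list, at 6.51 ± 0.903 and 1.18 ± 0.850 CPM (SD, n = 4). The 4 tested genes of the Gsdmc family all rose, with Gsdmc at a log2 fold change of 1.82 ± 0.27 (SE). The densest run of higher genes, 9 of 20 consecutive tested genes on chromosome 17 (37193892 to 44280169), included Mep1a and Enpp4 (permutation p = 0.029 over 10000 shuffles, median of the densest run by chance 7), and the densest run of lower genes had p = 0.36.

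All 7 genes from Hoxb3 to Hoxb9, neighbours on chromosome 11, rose in KO, with a median log2 fold change of 1.11, while the 8 tested Hox genes of groups 10 to 13 did not pass. The Hoxb3 span overlaps Hoxb4, so these 2 are not independent. GC content and gene length are argued against as the whole cause, since the median was 1.10 after the smooth, and lung RNA in KO replicate 6 is too, since it was 1.17 without that library. A shift of all Hox clusters along the colon axis may not account for it either, because the 8 tested genes of groups 3 to 9 in the other clusters had a median of -0.019 (quartiles -0.13 to 0.10). A difference between the mice or crypts from which the lines were grown stays open and was not tested.

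Fewer cell cycle transcripts with more colonocyte transcripts could reflect GC or length bias, but after the smooth the mitosis median was -0.33 (uncorrected -0.33, camera adjusted p = 9.8e-15) and the colonocyte median 0.39 (uncorrected 0.37, camera adjusted p = 4.4e-08), which argues against that trend as the whole cause. Without the smooth, neither list was called with an estimated correlation (adjusted p = 0.172 and 0.0988). An effect of the mouse or organoid line and not of the deletion cannot be told apart from genotype, because the labels allow as few as 1 mouse per genotype. The Cre recombinase used to make KO goes with genotype too, and its own effect was not tested. Reg3a had 0 counts in every WT library as in every KO library, so no loss of its transcript was detectable beside these changes. For each of the 4 gene counts, only 1 of 35 splits of the 8 libraries, the real one, gave as many genes (1140, 1234, 120 and 44, with at most 1 in any other split). This argues against a chance allotment of these libraries. It cannot exclude a chance difference between mice or lines, because the splits shuffle libraries that may come from 1 mouse per genotype. For lists called lower the real split was also the highest (11, highest other 8, 1 of 35 splits), at the preset correlation only, since 0 lists were called with an estimated one. For lists called higher a chance allotment was not excluded, since 6 of 35 splits, the real one included, gave at least 7 lists in 1 direction and the highest other gave 8. The 5 others each keep 3 KO libraries together.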
